A study of Drosophila melanogaster with 3 samples.

How the data were processed

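Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed with an antibody against green fluorescent protein on whole white prepupae of a transgenic Drosophila melanogaster line, per the labels. The line carries Cycle, the bHLH-PAS partner of Clock, fused to GFP at its C terminus, and animals of both sexes were pooled. Chromatin was fragmented by sonication, per the labels. The 3 samples are labelled as biological replicates of 1 group, so no comparison between groups was possible.

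The deposited files were peak lists in the narrowPeak layout, per the texts deposited with them. Each replicate had its own list of peaks and background regions, a pooled list was made from the 3 replicates together, and a list thresholded by the irreproducible discovery rate (IDR) was derived from these. Every list was deposited for the dm3 and dm6 assemblies. All lists of an assembly named the same control alignment, per the accompanying texts, and that control was not analysed here. The aligner, the peak caller and their versions are not given in the sources used here. The signal of each peak is the authors' value against that control. It was ranked or compared among peaks of the same list, or divided by a median of the same list. Ratios between replicates are given only as differences between X and the autosomes. The −log10 q value of each peak is also the authors' deposited value, and it was equal in all 7227 peaks of the thresholded dm6 list. It was therefore not used for ranking. The summit position is the offset deposited with each peak.

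The lists hold no read counts, so the depth of each sample is unknown and no precision could be derived from it. The dm6 lists of replicates 1, 2 and 3 held 30000, 30000 and 29999 peaks, with lowest signals of 11.3, 9.37 and 10.4. The pooled dm6 list held 29484 peaks. The thresholded list held exactly the 7227 pooled peaks with the highest signal. Exact binomial (Clopper-Pearson) 95% intervals, and the limit of 3 counts given in the text for a count of 0, describe counting error only, and tests over peaks treat peaks as independent although 372 neighbouring pairs of summits lay within 500 bp of each other.

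Coordinates are given on dm6. All dm6 peaks on the 6 chromosome arms (2L, 2R, 3L, 3R, 4 and X) ended inside the arms of the Release 6 sequence. Gene models came from Ensembl release 115 (build 6.54), with 13945 protein-coding genes and 19607 transcript starts on these arms. No dm3 reference was used here, so the dm3 lists served only for counts, overlap and agreement between replicates.

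Support was the share of thresholded peaks overlapped by at least 1 bp by the 7227 strongest peaks of a replicate. The replicate signal of a thresholded peak was that of the overlapping replicate peak nearest by summit. Relative signal was this value divided by its median over the thresholded peaks that had one in that replicate. It is given as mean ± SD over replicates. Neighbouring thresholded peaks can share a replicate peak. Summits were placed in exclusive classes in this order: within 1 kb of a protein-coding transcript start, 5' UTR exon, coding exon, 3' UTR exon, intron and intergenic. They were set against 10 uniformly drawn positions per peak, 72270 in all, that lay over 500 bp from any thresholded summit. Sequence was searched on both strands within 100 bp of the summit, in windows of 201 bp. These were set against 36135 control windows, 5 per peak, matched on distance to the nearest start (edges at 100, 250, 1000 and 5000 bp) and on GC content in bins of 2 percentage points, drawn from 800000 positions. A gene was called bound when a thresholded summit lay within 1 kb of any of its starts, so a summit between divergent genes counts for both. Tests of gene lists treat genes as independent, although members of a list can lie side by side on an arm.

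Shares were compared with Fisher's exact test, the share on X with an exact binomial test, and peak strength with a permutation test of 100000 resamples. All tests were two-sided, with Benjamini-Hochberg adjustment over location classes, the 6 arms, the 64 palindromic hexamers, the 17 preset motifs and the 19 gene lists, and a threshold of 0.05. The gene lists, motifs, tests and most alternatives were fixed before the data were examined. Of 522 list members, 6 had no match in the annotation. The genes named were fixed by rule: all 8 core clock genes, the gene nearest to each of the 15 strongest peaks, and the neighbours of cyc within 20 kb. The rule added up to 4 bound members with the highest signal of each other list that passed the threshold or dealt with ecdysone response, bHLH-PAS factors, clock kinases or circadian output. Alternatives varied the window, the controls, the overlap rule, the assembly, the stringency (the 3613 strongest thresholded peaks) and the replicates. Leaving out a replicate kept only thresholded peaks overlapped by the strongest peaks of both others.

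Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated data. A word planted to give a fold of 1.98 in 7000 windows was recovered at 1.86. The fold with nothing planted came out at 0.916 in place of 1 (exact p = 0.371) and averaged 1.02 ± 0.0827 (SD) over 20 repeats. Of 500 random gene lists, 0 passed the adjusted threshold. Binding was drawn independently for each gene there, so clustered families were not simulated.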

Results

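The binding of GFP-tagged Cycle was profiled by ChIP-seq in whole white prepupae, the stage at which the larva has just formed the puparium. Cycle pairs with Clock to activate the circadian genes of the fly through the E-box CACGTG. The 3 biological replicates form a single group, and the thresholded list derived from them held 7227 peaks on dm6 with a median width of 410 bp. The signal is the authors' own value for each peak, and it ran from 110.3 to 5704.7 with a median of 212. Read depth is unknown.

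The first question was how far the replicates share these peaks. The list was derived from these same replicates, so agreement over its peaks is partly built in, and no expected value was computed. The 7227 strongest peaks of replicate 1 overlapped 83.0% of the thresholded peaks (95% interval 82.1 to 83.9%). The corresponding shares were 87.1% (86.3 to 87.9%) for replicate 2 and 88.3% (87.5 to 89.0%) for replicate 3, a mean of 86.1% ± 2.76 (SD, n = 3). All 3 replicates supported 4926 peaks, and 22 peaks had support from none of these sets. Across peaks, which are not independent replicates, Spearman's rho of the signal was 0.808 between replicates 1 and 2, 0.686 between 1 and 3, and 0.747 between 2 and 3. Each rho covers only the thresholded peaks with a peak in both replicates, 6570, 6558 and 7096 in this order. The relative signal had a median coefficient of variation of 22.9% over the replicates, among the 6514 peaks present in all 3. Peaks missing from a replicate are thus left out of these measures of agreement.

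The strongest peak of the list lay on 3L, 97 bp from a start of CG14100 (19589072 to 19590524), with a relative signal of 26.9 ± 6.73 (SD, n = 3). The next lay on X, 34 bp from a start of Ugalt, which encodes a UDP-galactose transporter (2701124 to 2703852), at 24.6 ± 4.35 (SD, n = 3). The third summit, on 2L, had its nearest start 1370 bp away at cbt, a zinc finger gene (476446 to 479688), but lay outside cbt in an intron of ush (476220 to 540560), at 21.5 ± 6.58 (SD, n = 3). PNPase on 3R (31401560 to 31405452) followed at 19.7 ± 4.41, and Lk6, a kinase gene on 3R (11750931 to 11764457), at 17.8 ± 3.22 (both SD, n = 3). The other genes nearest to the 15 strongest peaks were Chro, which encodes a chromodomain protein, CG11050, CG1888, Tcs5, CenG1A, Art3, CG16753, osa, a Brahma complex gene, CG32772 and ph-p, a Polycomb group gene. Of these, the summits for CG11050, osa and CG32772 lay in an intron of that gene, the one for osa 13932 bp from the nearest start. The summit with CG16753 as its nearest start, 5726 bp away, lay outside that gene in an intron of CG32486 (3L, 3055908 to 3070839). None of the 15 strongest summits had CACGTG within 100 bp.

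Cycle summits were concentrated at gene starts. Within 1 kb of a protein-coding transcript start lay 47.9% of the summits (46.7 to 49.0%), against 19.3% of uniform positions, an odds ratio of 3.85 (95% interval 3.66 to 4.05). The exact p of this comparison was too small to be represented. Introns over 1 kb from a start held 32.5% of all summits against 36.3% of all uniform positions (adjusted exact p = 1.01e-10, Fisher's exact test). Intergenic sequence held 18.7% against 28.5% (adjusted exact p = 2.25e-76). Every share here is of all positions, so the larger share near starts lowers those of the other classes. The intron and intergenic values thus show no depletion among positions over 1 kb from a start, which were not compared separately. Coding exons over 1 kb from a start held 7 of 7227 summits, or 0.0969% (0.0390 to 0.199%), against 11.5% of uniform positions. The 3' UTR exons held 0.678% against 3.90% (adjusted exact p = 5.85e-63), and 5' UTR exons 0.166% against 0.482% (adjusted exact p = 2.95e-05). Pooled peaks that overlapped no thresholded peak were also frequent near starts, at 31.2%, so the odds ratio fell to 2.03 with these as controls.

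**Figure D1:**
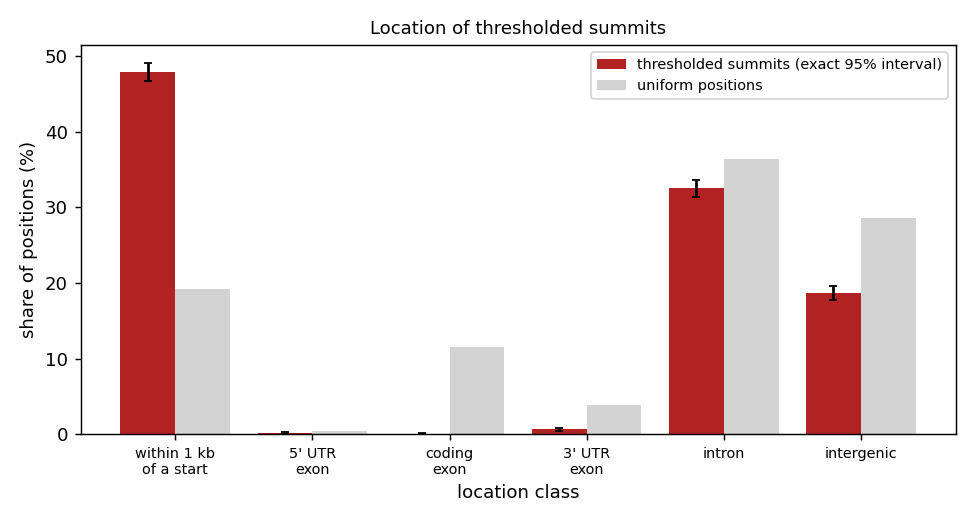
Share of the 7227 thresholded summits (red bars, with exact 95% intervals) and of 72270 uniform positions (grey bars) in each exclusive location class, in percent. Summits are more frequent within 1 kb of a start (47.9% against 19.3%) and nearly missing from coding exons farther away (0.0969% against 11.5%).

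No excess of the E-box of Clock and Cycle was detected at the summits over matched controls. CACGTG lay within 100 bp of 118 of 7227 summits, or 1.63% (1.35 to 1.95%), and in 592 of 36135 control windows, or 1.64% (1.51 to 1.77%). The odds ratio was 0.997 (95% interval 0.809 to 1.22; Fisher's exact test, p = 1.0). Among the 64 palindromic hexamers CACGTG ranked 38 by fold. GTGCAC ranked first, with 8.36% of summits against 3.18% of controls (fold 2.63, adjusted exact p = 9.61e-75), followed by GGCGCC (fold 1.99, adjusted exact p = 6.47e-15). Against flanks 1 kb from the same summits, CACGTG was less frequent at the summits (fold 0.720, exact p = 0.00164). These flanks were not matched on GC content or distance to starts, and Fisher's exact test did not use their pairing with the summits.

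Of the 17 preset motifs, 8 were more frequent at summits than in matched controls and 2 less frequent. The largest fold, 2.16, was that of TATCGATA, the sequence of the factors DREF and BEAF-32 (adjusted exact p = 1.60e-20). GGTCACAC, the M1BP sequence of core promoters, had a fold of 1.88 (adjusted exact p = 2.50e-09), and GAGAGA, the site of GAGA factor, 1.54 (adjusted exact p = 2.37e-22). Among the E-box classes, CAGCTG had a fold of 1.46 (adjusted exact p = 8.84e-15), CACATG 1.16 (adjusted exact p = 0.00239), CATATG 1.15 (adjusted exact p = 0.00567) and CAAGTG 1.11 (adjusted exact p = 0.00768). The composition control AAAAAA also passed, with a fold of 1.11 (adjusted exact p = 7.45e-14), while CGCGCG did not (fold 1.19, adjusted exact p = 0.226). The odds ratio of AAAAAA, 1.22, was above those of CACATG (1.18), CATATG (1.16) and CAAGTG (1.12). The small excesses of these E-box classes therefore cannot be told apart from a remaining difference in base composition. CAATTG (fold 0.875, adjusted exact p = 0.00460) and CAAATG (fold 0.916, adjusted exact p = 0.00239) were less frequent. CAGGTAG, the Zelda site, had a fold of 1.12 (adjusted exact p = 0.446).

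**Figure D2:**
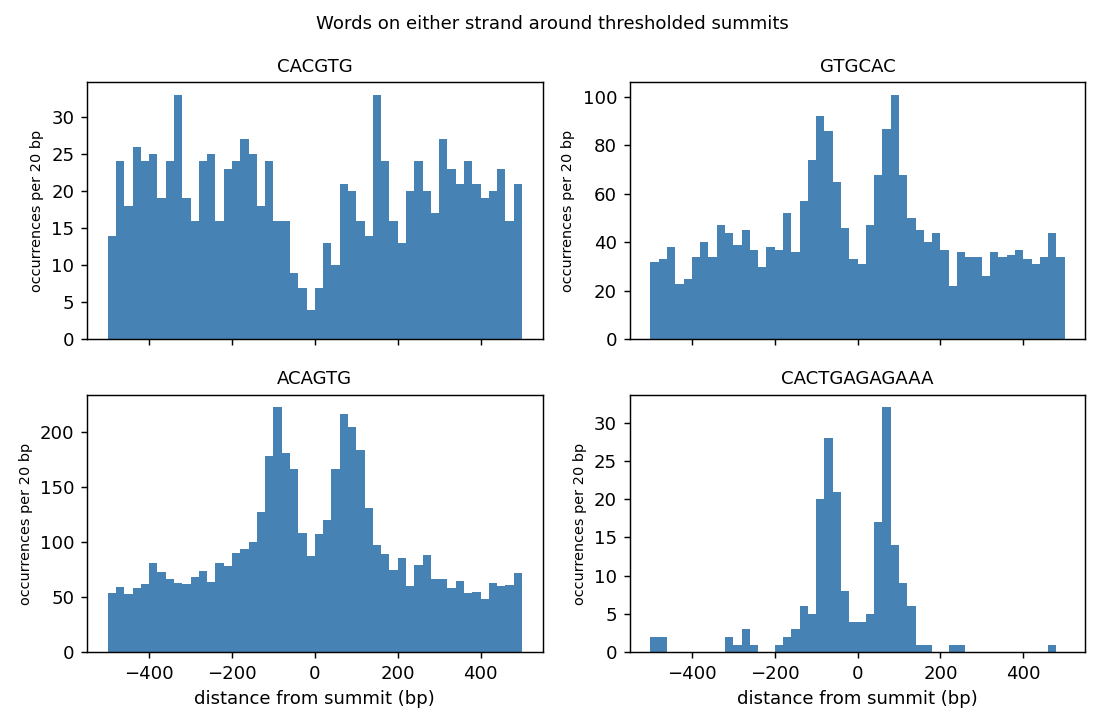
Occurrences of 4 words on either strand in bins of 20 bp (vertical axis) by distance from the thresholded summit in bp (horizontal axis). CACGTG is sparse at the summit, with 11 occurrences within 20 bp, while GTGCAC, ACAGTG and CACTGAGAGAAA rise on both sides of it.

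No difference in strength was detected between peaks with and without the E-box. The median signal was 218 in the 118 peaks with CACGTG and 212 in the 7109 without, a difference of 0.04 on the log2 scale (permutation test, p = 0.738). With the peaks split by rank into 10 sets of equal size, the share with CACGTG ran from 1.24 to 2.35%, and it was 1.80% (0.962 to 3.06%) in the 722 strongest peaks.

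Of the 8 core clock genes, vri, Pdp1 and cry had a thresholded summit within 1 kb of a start. This share of 37.5% (8.52 to 75.5%) was not distinguishable from the 28.6% of other protein-coding genes (odds ratio 1.5, adjusted exact p = 0.865, Fisher's exact test). The gene vri (2L, 5288944 to 5311223), which encodes a bZIP repressor of Clk, had its summit 223 bp from a start, with a relative signal of 1.04 ± 0.424 (SD, n = 3). It held 7 thresholded summits in all, the strongest an intronic one with a signal of 849.9. Pdp1 (3L, 7811458 to 7867369), whose bZIP product acts on the clock loop opposite to vri, had its summit 472 bp from a start at 0.944 ± 0.799 (SD, n = 3), and held 6 thresholded summits. Of these, only an intronic summit at position 7863836 had CACGTG within 100 bp. The gene cry (3R, 19212154 to 19215442), the blue-light photoreceptor gene, had its summit 230 bp from the start at 1.84 ± 0.178 (SD, n = 3).

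The other 5 core clock genes had no thresholded summit within 1 kb. The nearest one to per (X, 2685580 to 2692780) was 18306 bp away, and that to tim (2L, 3493986 to 3508119) 25251 bp. For cwo (3R, 10388258 to 10400752), which encodes a bHLH-Orange repressor, it was 23675 bp away, and for Clk (3L, 7763233 to 7775603) 7950 bp. The unthresholded pooled list held peaks within 1 kb of starts of per, tim and cwo, the strongest ranking 17338, 21160 and 10211 of 29484, and none for Clk. Of all protein-coding genes, 55.4% had a pooled summit this close. The best ranks in any single replicate list were 14633 for per, 7138 for tim, 8996 for cwo and 19893 for Clk. The nearest thresholded summit to a start of cyc (3L, 19813770 to 19815938) was 2039 bp away and lay 10 bp from a start of Fibp. Fibp and Deaf1, which share this peak within 1 kb, had a relative signal of 3.77 ± 0.251 (SD, n = 3). A weaker thresholded summit at position 19818179, 5 bp from a start of Deaf1 and 2241 bp from that of cyc, had relative signals of 0.247 in replicate 1 and 1.93 in replicate 3. In replicate 2 a single peak, at 3.92, was counted for both summits. Of the other neighbours of cyc within 20 kb, SREBP had a bound start, and Ccdc58, CG14102, TORIP, Ir76a, CG14104, CG32221, trc, Kap-alpha1, Cyp305a1 and CG34116 had none. The tagged transgene can add copies of this region. Its 42169 bp held 5 pooled peaks, against a median of 8 in windows of this length. The replicate lists differed here, with 3 peaks in replicate 1 (median 10), 15 in replicate 2 (median 8) and 9 in replicate 3 (median 8). All these counts lay within the 5th to 95th percentiles of other windows. The percentiles were 0 to 23 for the pooled list, 0 to 19 for replicate 1, and 0 to 25 for replicates 2 and 3. Replicates 2 and 3 each had 2 peaks within 1 kb of the start of cyc, the strongest ranking 2971 and 5893, and replicate 1 had 0.

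Of the 18 other preset gene lists, 6 differed from other protein-coding genes in the share of bound genes. Cytosolic ribosomal protein genes were bound most often, 74 of 92, or 80.4% (70.9 to 88.0%; adjusted exact p = 1.06e-23, Fisher's exact test). RpS27 had a relative signal of 5.70 ± 0.129, RpL32 of 4.98 ± 1.01, RpS19b of 4.56 ± 1.15 and RpL7 of 4.46 ± 0.584 (each SD, n = 3). Odorant, gustatory and ionotropic receptor genes were bound least often among lists with a bound member, 4 of 179, or 2.23% (0.612 to 5.62%; adjusted exact p = 6.90e-20). The 4 were Ir94h, Or9a, Ir60e and Gr32a. The share fell to 1.12% without replicate 2 or 3, against 20.1% and 20.3% of other genes. With a window of 500 bp it was 0.559%, against 25.1%.

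Genes for the kinases, phosphatases and degradation factors of the clock were bound in 9 of 13 cases, or 69.2% (38.6 to 90.9%; adjusted exact p = 0.0130, Fisher's exact test). The strongest were sgg, the GSK3 kinase gene, at 5.28 ± 0.548, and Fbxl4 at 3.43 ± 0.433. They were followed by dco, the casein kinase 1 gene, at 3.12 ± 0.921, and mts, the catalytic subunit gene of protein phosphatase 2A, at 1.65 ± 0.586 (each SD, n = 3). This list did not pass without replicate 2 (adjusted exact p = 0.0918) or without replicate 3 (adjusted exact p = 0.0816), each time with 46.2% bound. Nor did it pass among the 3613 strongest peaks, at 46.2% against 16.7% of other genes (adjusted exact p = 0.0618). It also missed the threshold against genes with a pooled peak, where 75% of the list and 51.5% of the others were bound (adjusted exact p = 0.402). Cell cycle and growth genes had the same count, 9 of 13 (adjusted exact p = 0.0130, Fisher's exact test). Among them stg, the Cdc25 phosphatase gene, reached 4.63 ± 1.58 and CycE 1.52 ± 0.925, while Mnt stood at 1.49 ± 0.0976 and Cdk1 at 1.46 ± 0.0880 (each SD, n = 3). This list did not pass without replicate 1, at 46.2% bound against 24.2% of other genes (adjusted exact p = 0.231). Without replicate 2 it did not pass either, at 38.5% against 19.8% (adjusted exact p = 0.323). It also missed the threshold with windows of 500 bp, at 53.8% against 24.7% of other genes (adjusted exact p = 0.0877), and 5 kb, at 84.6% against 50.7% (adjusted exact p = 0.0614). The same held against genes with a pooled peak, at 81.8% against 51.5% (adjusted exact p = 0.211), and among the 3613 strongest peaks, at 38.5% against 16.8% (adjusted exact p = 0.161).

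None of 19 cuticle and epidermis genes was bound (a count of 0 allows up to 15.8%; adjusted exact p = 0.0130, Fisher's exact test), and none of 15 salivary glue and late puff genes (up to 20%; adjusted exact p = 0.0280). Leaving out a replicate only removes peaks, so both lists had to stay at 0 bound. The share of other genes fell to between 19.9 and 24.3%. Against these lower shares the glue list did not pass without replicate 1, 2 or 3 (adjusted exact p = 0.109, 0.127 and 0.112), and the cuticle list did not without replicate 2 or 3 (adjusted exact p = 0.0918 and 0.0664). The 3613 strongest peaks are part of the same list, so 0 bound was fixed there too, against 16.8% of other genes. Neither list passed there (adjusted exact p = 0.328 and 0.161 for glue and cuticle), nor did the glue list with a window of 500 bp (adjusted exact p = 0.0959). Both passed with a window of 5 kb, with 1 of 15 glue and 3 of 19 cuticle genes bound (adjusted exact p = 0.00274 and 0.00851). They also passed with summits anywhere in the gene body (adjusted exact p = 0.0133 and 0.00406). Against genes with a pooled peak, where 0 bound was again fixed, each had 0 of 8 against 51.6% (adjusted exact p = 0.0143). Ecdysone response genes were bound in 11 of 22 cases, or 50% (28.2 to 71.8%), which missed the threshold (adjusted exact p = 0.0788). Their strongest members were the cell death gene hid at 5.35 ± 1.29, Ldh at 3.81 ± 1.05, and the nuclear receptor genes Hr3 at 3.91 ± 0.547 and Eip75B at 3.39 ± 0.580 (each SD, n = 3). This list passed with a window of 5 kb, at 86.4% against 50.7% of other genes (adjusted exact p = 0.00415). It also passed with summits anywhere in the gene body, at 72.7% against 32.3% (adjusted exact p = 0.000779), and without replicate 3 (adjusted exact p = 0.0266). Against genes with a pooled peak it did not pass, at 55% against 51.6% (adjusted exact p = 0.980). Nor did it with a window of 500 bp (adjusted exact p = 0.205), among the 3613 strongest peaks (adjusted exact p = 0.189), or without replicate 1 or 2 (adjusted exact p = 0.113 and 0.0918). No list test accounted for gene length or number of starts.

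The remaining lists did not pass the threshold. Glycolysis genes were bound in 9 of 16 cases (adjusted exact p = 0.0628), and this list passed without replicate 2 (adjusted exact p = 0.0422), without replicate 3 (adjusted exact p = 0.0266) and with summits anywhere in the gene body (adjusted exact p = 0.0349). The count was 5 of 11 for detoxification genes (adjusted exact p = 0.496) and 5 of 11 for bHLH-PAS and co-activator genes (adjusted exact p = 0.496). In the bHLH-PAS list, nej, the CBP gene, stood at 1.86 ± 0.448, the juvenile hormone receptor gene gce at 1.30 ± 0.708, tai at 1.08 ± 0.506 and trh at 0.795 ± 0.628 (each SD, n = 3). Circadian output genes were bound in 5 of 15 cases (adjusted exact p = 0.865), led by amon, a prohormone convertase gene, at 5.05 ± 1.20, qsm at 1.83 ± 0.279 and Hk at 1.59 ± 0.162 (each SD, n = 3). The fourth, nocte, had a peak in replicates 2 and 3 only. Heat shock genes were bound in 7 of 23 cases (adjusted exact p = 0.865), fat body genes in 4 of 12 (adjusted exact p = 0.865) and ecdysone synthesis genes in 2 of 8 (adjusted exact p = 1.0). Neuron genes were bound in 3 of 16 cases (adjusted exact p = 0.788), muscle genes in 3 of 18 (adjusted exact p = 0.632), gut genes in 2 of 15 (adjusted exact p = 0.491) and haemocyte genes in 0 of 10 (adjusted exact p = 0.152).

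**Figure D3:**
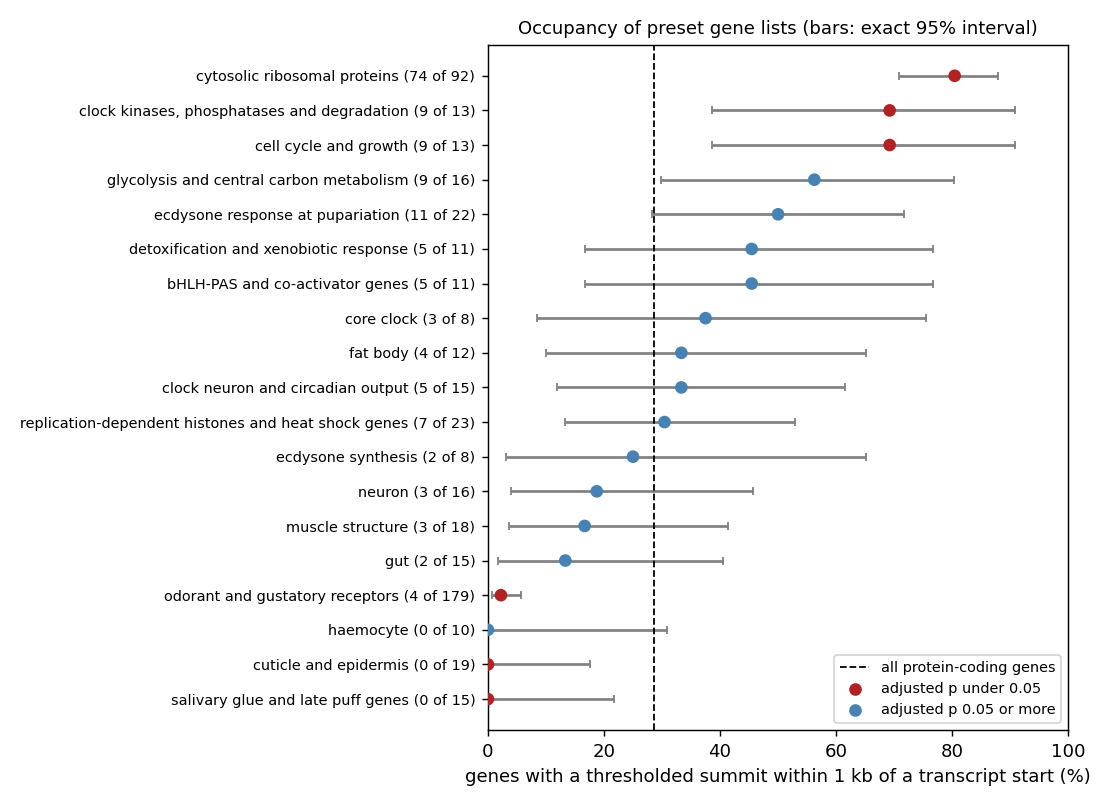
Share of genes in each preset list with a thresholded summit within 1 kb of a transcript start, in percent, with exact 95% intervals, red where the adjusted p is under 0.05. The dashed line marks the 28.6% of all 13945 protein-coding genes, and ribosomal protein genes lie highest, at 80.4%.

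On the X chromosome lay 1419 summits, or 19.6% (18.7 to 20.6%), against 16.9% of protein-coding transcript starts (exact binomial test, p = 8.88e-10). X was not alone in departing from its share of starts. The arm 3L had 21.8% of summits against 19.3% of starts (adjusted exact p = 2.04e-07) and 2R had 17.2% against 20.6% (adjusted exact p = 3.88e-12). Chromosome 4 had 0.401% against 0.724% (adjusted exact p = 0.000962), 2L had 17.7% against 18.8% (adjusted exact p = 0.0177), and 3R had 23.2% against 23.7% (adjusted exact p = 0.354). The shares of arm length were 17.6% for 2L, 18.9% for 2R, 21.0% for 3L, 24.0% for 3R, 1.01% for 4 and 17.6% for X. Against length 2L thus showed no deficit and the excess on 3L was smaller. X stayed above its share of length (exact binomial test, p = 6.39e-06), and the other arms were not tested against length. The 7227 strongest peaks of replicate 1 taken alone had 17.3% on X which was not distinguishable from the share of starts (exact binomial test, p = 0.388). The corresponding sets of replicates 2 and 3 had 20.8% and 19.6%.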

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

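The dm6 list of replicate 3 held 32 peaks on the mitochondrial genome, which lies outside the chromosome arms analysed, and the dm6 lists of replicates 1 and 2 held 0 each. With no control sample in the series, the number was set against the 3 that a count of 0 allows, which covers counting error only. Their signal ran from 15.2 to 407 with a median of 117, and 27 of them ranked among the 7227 strongest peaks of that replicate. The number varied with the assembly, as the dm3 list of replicate 3 held 5 mitochondrial peaks. The pooled list held 0 on dm6 and 2 on dm3, and none was in the thresholded list.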

How the results depend on the processing

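Alternatives by the strongest summit within 500 bp, by single replicate lists on X, by summits in the gene body for lists other than the core clock, and those leaving out a replicate for support and agreement were chosen after seeing the data. Mean support moved to 71.1% with reciprocal overlap of 50%, 82.3% with summits within 100 bp, 96.6% with all replicate peaks, 95.8% with 14454 replicate peaks and 97.9% in the 3613 strongest thresholded peaks. The cause was not tested. With 1 replicate left out, mean support over the other 2 ran from 85.0 to 87.7%, and rho was that of the remaining pair, from 0.686 to 0.808. These restate the values of single replicates and pairs given above and are no further check. The share near starts stayed above its controls in every alternative run, from 45.1 to 49.7% without each replicate. The sets without replicate 1, 2 or 3 hold 5698, 5313 and 5380 of the same thresholded peaks. No list was derived anew from 2 replicates, so all settings without a replicate, here and below, are only a weak check. The fold of CACGTG was 1.11 with 250 bp to each side (exact p = 0.0522), 0.720 against flanks (exact p = 0.00164), 1.04 with the strongest summit within 500 bp, and 0.950 to 1.03 without each replicate. The cause was not tested. Only the comparison with flanks, which were not matched on GC content or distance to starts, passed the threshold. The log2 difference in strength was -0.0632 with the signal of replicate 2, -0.0128 with that of replicate 3 and -0.00965 to 0.0492 without each replicate, and no setting passed.

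The core clock share was 50% with a window of 5 kb and 50% among genes with a pooled peak, each just below the share of other genes, and 25 to 37.5% without each replicate. No setting passed. The number of other lists that passed fell from 6 to 2 with the 3613 strongest peaks, and to between 3 and 5 without each replicate, where fewer peaks leave fewer bound genes, and was 8 with the gene body. Over 162 settings of single lists, 130 kept direction and side of the threshold, 18 lost the threshold, 6 passed it and 8 turned direction, none of these past it. The turned shares were 40.0% (5 kb) and 41.7% (genes with a pooled peak) for circadian output, 62.5% (5 kb) for ecdysone synthesis, 40.0% for fat body and 100% for gut (both among genes with a pooled peak), and 47.8% (5 kb), 50% (genes with a pooled peak) and 30.4% (gene body) for heat shock genes. The cause was not tested. The share on X lost its call only with the strongest peaks of replicate 1, at 17.3%, and ran from 18.5 to 20.2% without each replicate. No paired analysis was possible because the samples form 1 group. Depth is unknown and limits what the weakest peaks can show.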

Other observations

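The gene families in this part, the words other than CACGTG and GTGCAC, and the tests on the 722 and 3613 strongest peaks and on transposable elements were chosen after seeing the data; the tests on distal peaks, reordered words and coding exons had their outcome bounds set before their results were seen.

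Among 12 gene families taken by symbol, genes of mitochondrial ribosomal proteins were bound in 37 of 73 cases, or 50.7%, against 28.5% of other genes (adjusted exact p = 0.000216, Fisher's exact test). Of 12 insulator and chromatin protein genes 10 were bound, but this family was put together after Chro had been seen among the strongest peaks, so no test of it is given. Cytochrome P450 genes (7 of 85), Cpr cuticle protein genes (5 of 70) and odorant-binding protein genes (2 of 51) were bound less often (adjusted exact p = 5.59e-05 each). So were Twdl cuticle protein genes (0 of 25, adjusted exact p = 0.000924), Osiris genes (1 of 25, adjusted exact p = 0.00590) and Jonah protease genes (0 of 16, adjusted exact p = 0.0141). These tests count each gene as independent, so a family whose members lie side by side can pass too easily. Proteasome, translation initiation factor, complex I and aminoacyl-tRNA synthetase genes did not pass the threshold (adjusted exact p = 0.367, 0.295, 0.600 and 0.238). The Cpr, Jonah and cytochrome P450 families share members with preset lists, so their tests partly repeat those of the lists.

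The whole list of replicate 1 had 11.9% of its 30000 peaks on X, against 22.1% and 21.8% in replicates 2 and 3. Among the 1000 strongest peaks of each list the shares were 17.8% in replicate 1, 21.3% in replicate 2 and 17% in replicate 3. The low share of replicate 1 thus lay mainly among its weaker peaks. Peaks found only in replicate 1 numbered 13893, with 5.82% on X, while those found only in replicates 2 and 3 had 25.3% and 23.7%. Such peaks were weak in replicates 1, 2 and 3, with median signals of 14.0, 12.4 and 14.2. Shared peaks had medians of 25.3, 23.2 and 27.9. At thresholded peaks the log2 ratio of replicate 1 to replicate 2 was lower on X than on the autosomes, by a difference of -0.23 (bootstrap 95% interval -0.26 to -0.18), and the difference for replicate 1 to replicate 3 was -0.05 (-0.11 to 0.00). For replicate 2 to replicate 3 it was 0.15 (0.11 to 0.18). These ratios cover only peaks present in both replicates. Replicate 1 had no peak at 12.4% of the thresholded peaks on X and 7.08% of those on autosomes, against 0% and 1.21% in replicate 2 and 0.211% and 1.45% in replicate 3.

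The missing excess of CACGTG was the first pattern weighed. Peaks over 1 kb from a start had an odds ratio of 0.896 (0.641 to 1.23), which argues against promoter peaks hiding a distal excess of 1.5 or more. The 3613 strongest peaks gave 0.987 (0.733 to 1.31), which argues against weak peaks diluting such an excess spread over the stronger ones. An excess confined to the 722 strongest stays open, because these gave 1.25 (0.623 to 2.35). Recovery of open chromatin without regard to sequence was not tested, since the control was not analysed here, and no biological explanation was tested.

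A second pattern was a set of related words beside the summits. Of the 10 hexamers with the highest fold among peaks on 2L, 2R, 4 and X, all 10 were more frequent than in matched controls on 3L and 3R, led there by GTGCAC (fold 2.76) and CAGTGC (fold 2.58). The longer word CACTGAGAGAAA lay near 144 summits, or 1.99%, against 0.0747% of controls (fold 26.7), and 170 of its 688 occurrences on the arms lay in thresholded peaks, which cover 1.79% of the arms. Copies in annotated transposable elements were argued against, with 0% of the 148 copies within 100 bp of a summit in such an element (a count of 0 allows up to 2.03%) and 3 of all 688, although elements cover 5.93% of the arms. For 100 reordered words together the fold was 1.02 (0.631 to 1.65), so no excess was detected for words of the same base composition. The controls were already matched on GC content, and the longer word, unlike the reordered ones, was chosen after seeing these peaks. The comparison therefore cannot decide whether base composition or the choice of the word contributed to its fold. The word may mark sites of another factor or of a shared chromatin state, and no biological explanation was tested.

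The third pattern was the scarcity of summits in coding exons, counted here at any distance from a start. Coding exons held 35 of 7227 summits, or 0.484% (0.338 to 0.673%), and 4.94% of the pooled summits outside thresholded peaks. Base composition and distance to starts were argued against as the whole cause, since 7.13% (6.86 to 7.40%) of the matched controls lay in coding exons. A shift of summits off exons inside the peaks was argued against as the whole cause. Coding exons made up 1.47% of peak bases and 17.1% of the arms, a ratio of 0.0863. The 1.47% is above the 0.484% of summits, so such a shift may account for part of the scarcity. The arms as a whole are not matched, unlike the controls with 7.13%. A higher background of the control over coding sequence may remain as a technical source, and no biological explanation was tested.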
